A study of Homo sapiens with 6 samples.

How the data were processed

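Poly(A) RNA-seq libraries were made from total RNA of MV4-11 cells, 3 with a PRMT5 hairpin and 3 with a scrambled hairpin, per the labels' protocols. The deposited values are estimated counts per gene for each library, 1 table per library, not scaled to depth. The submitters' processing notes name CASAVA 1.9, TopHat2 version 2, edgeR and the genome build hg19, with no role or order. The counting tool, its gene annotation and any use of strand are not given in the sources used here. Antisense, overlapping and near-identical genes can therefore share reads. From the values themselves, 40.3% to 42.3% of entries were whole (tolerance 1e-06), and at least 99.9958% were whole after multiplication by 51 (tolerance 0.001), so parts of reads were credited to genes. Values were rounded to whole numbers before any count model. Gene symbols are those of the deposited tables, and 108 rows carry a symbol that occurs at more than 1 place. The annotation at hand was of another genome build, so chromosomes are given as deposited and no coordinates are printed.

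Library totals were 16408484 to 19077106 counts. Counts of reads without molecular identifiers are not independent molecules, so a low count carries counting error and amplification error. Nothing in the labels says that the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

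Genes kept by filterByExpr (minimum count 10, grouping by condition) were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, estimateDisp, glmQLFit and glmQLFTest, with the group as the only term, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. All adjusted p-values of single genes come from that edgeR model unless another tool is named. Fold changes are knockdown minus control on the log2 scale. SEs and 95% intervals were taken from the quasi-likelihood fit. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. An exact permutation of 3 against 3 libraries cannot give a p under 0.1, so single values were not tested that way.

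The test, the samples, 30 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 28 lists. An estimated correlation was the alternative for that comparison. fry was also run; it tests whether a list's genes move on balance in one direction and does not compare them with other genes. The B cell list had too few tested genes, and the mitochondrial list was not analysed here. Named genes were PRMT5, WDR77, FLT3, SP1, DNMT3A, DNMT3B and the MIR29 genes; the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between groups, a set that was empty; the 5 smallest p-values in each direction; and up to 4 members per list with the smallest p-values. Genes without an official symbol were skipped, and 2 list members that the rule names are not reported here singly.

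The titles give both groups the numbers 1 to 3, and nothing in them states that a number marks a shared day or batch. Whether the numbers pair the libraries was checked by correlating deviations from the group means over genes. For same-numbered libraries r was 0.127, 0.394 and 0.566, each above 0.1, so these libraries are described as pairs below. The main fit had no term for the pairs. Of the 6 combinations with different numbers, knockdown 2 with control 1 had r = 0.164, above that of pair 1, and the other 5 had −0.581 to −0.00906. In log2 CPM, knockdown 2 correlated with control 1 at 0.976 and with the library labelled scrambled control 2 at 0.909. The pairing thus comes from the values, not from the labels. The fit with the replicate number as a block was an alternative.

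Other alternatives were RLE, upper quartile and total-count scaling, 2 other filters on low counts, DESeq2 1.42.0, limma-voom, a 2-fold minimum, a glmTreat test against a 1.2-fold change, and each library left out in turn. GC content and transcript length came from GENCODE v29 transcripts and were matched by symbol for 12208 of the tested genes (89.3%).

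The scripts were tested on simulated data for the comparison of knockdown with control over 13668 genes, with 200 seeded genes, 50 per fold size. Seeded genes were drawn only from those with a mean of at least 5 CPM, so recovery below that level is not known. With negative binomial draws, edgeR recovered 8% of 2-fold, 80% of 4-fold, 98% of 8-fold and 100% of 16-fold changes, with 11 false calls. With changes added to the deposited counts it recovered 0%, 72%, 82% and 98%, with 0 false calls. There the other genes kept their deposited counts, among which no gene passed, so the 0 false calls says little about the rate of false calls. In the simulated list test, only the seeded list was called. Its genes were drawn independently, so it cannot show how the preset correlation of 0.01 performs on correlated genes. In the data, the estimated correlation ranged from −0.027 for the genes reported as repressed by PRMT5 to 0.935 for cytosolic ribosomal proteins.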

Results

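RNA-seq was run on MV4-11, an established acute myeloid leukaemia line that carries the FLT3 internal tandem duplication and an MLL rearrangement. Cells stably transduced with a lentiviral short hairpin RNA against PRMT5, the main enzyme of symmetric arginine dimethylation, formed 1 group of 3 libraries. Cells transduced with a scrambled hairpin formed the other group of 3. The libraries held 16408484 to 19077106 estimated counts over 23698 gene rows, totals being rounded to whole numbers. By library, the total was 19077106 in knockdown 1, 16408484 in knockdown 2 and 17734124 in knockdown 3. It was 17025703 in control 1, 17525747 in the library labelled scrambled control 2 and 18553733 in control 3. Between 16870 and 17295 rows had a count in each library, and 13668 genes entered the tests.

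PRMT5, on chromosome 14, averaged 76.0 ± 25.5 CPM (counts scaled to depth with TMM factors; SD, n = 3) in the knockdown libraries and 115 ± 55.0 CPM (SD, n = 3) in the controls. The knockdown libraries held 103, 71.6 and 52.99 CPM. Controls 1 and 3 held 133 and 158 CPM, above every knockdown library. The library labelled scrambled control 2 held 53.2 CPM, a level of the knockdown group, so its PRMT5 value goes against its label. The low value was not particular to PRMT5. The list of PRMT family and partner genes, PRMT5 included, had a median log2 difference of −0.97 in that library against controls 1 and 3. PRMT3 and RIOK1 were lower there too, while PRMT2 was higher. For PRMT5 the log2 difference of knockdown minus control was −0.60 (SE 0.43, 95% confidence interval −1.60 to 0.41). It did not pass the test (adjusted p = 0.926, edgeR quasi-likelihood). Between libraries with the same number it was −0.36 in pair 1, 0.43 in pair 2 and −1.58 in pair 3, where PRMT5 was 2.99-fold lower in the knockdown library. Without the library labelled scrambled control 2 the difference was −0.94, and without control 3 it was −0.29. Without knockdown 3 it was −0.40.

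**Figure D1:**
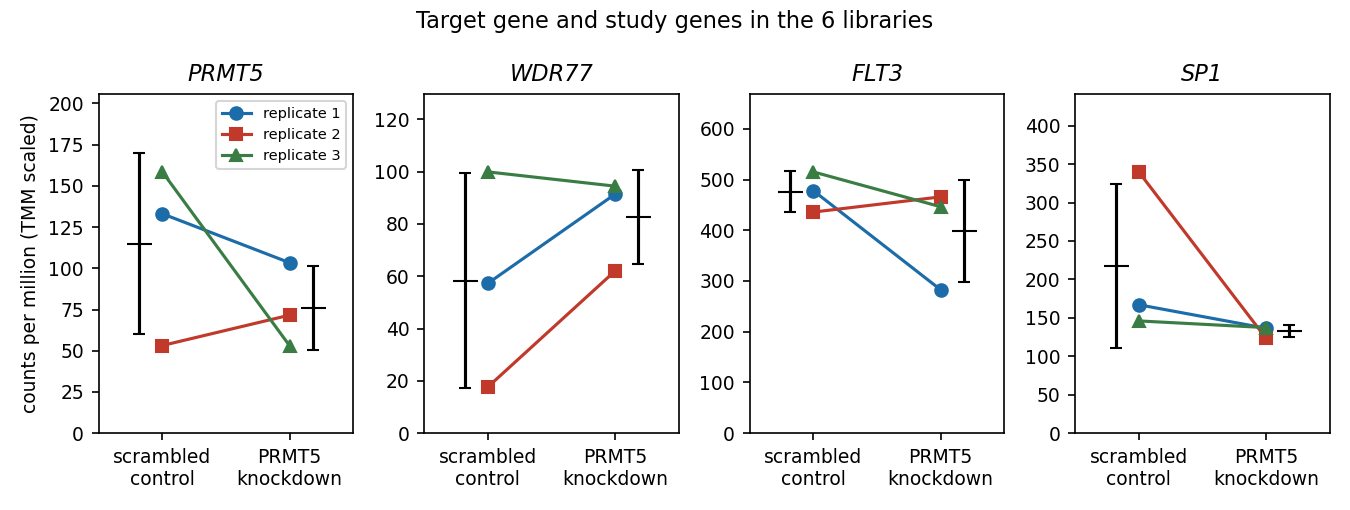
Expression of PRMT5, its cofactor gene WDR77, FLT3 and SP1 in each library, in TMM-scaled CPM on linear axes from 0; lines join libraries with the same replicate number, and black bars give the mean and SD of each group (n = 3). PRMT5 was 53.2 CPM in the library labelled scrambled control 2 and 133 and 158 CPM in the other controls, and SP1 in that library was 340 CPM.

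The other genes of the study's question were measured in the same fit, and none passed it. WDR77, which encodes the MEP50 partner of PRMT5, was at 82.6 ± 17.9 CPM (SD, n = 3) in the knockdown and 58.3 ± 41.1 CPM in the control libraries, a log2 difference of 0.50 (SE 0.55). The control values were 57.2 and 99.9 CPM in controls 1 and 3 and 17.6 CPM in the library labelled scrambled control 2, without which the log2 difference was 0.07. FLT3, the receptor kinase mutated in this line, was at 398 ± 101 and 476 ± 39.6 CPM, a log2 difference of −0.26 (95% confidence interval −0.84 to 0.33). SP1, a zinc-finger transcription factor, was at 132 ± 7.85 and 218 ± 106 CPM, a log2 difference of −0.72 (95% confidence interval −1.50 to 0.07). The control mean of SP1 included 340 CPM in the library labelled scrambled control 2, beside 167 and 146 CPM in controls 1 and 3, and without that library the log2 difference was −0.24. The DNA methyltransferase genes DNMT3A and DNMT3B had log2 differences of −0.07 (SE 0.33) and −0.32 (SE 0.38). All 6 genes had an adjusted p of 0.926 or above in edgeR, that of DNMT3A being 0.976. The miR-29 genes were at the floor of this poly(A) assay: the MIR29C row held 0.667 to 8.33 counts per library, MIR29B2 at most 1.10, and MIR29A and MIR29B1 held 0. These poly(A) libraries therefore did not measure miR-29, and no miR-29 host gene was read out.

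No gene separated the knockdown from the control libraries after correction. With edgeR's quasi-likelihood test, 0 of 13668 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.926. At an unadjusted p under 0.05 there were 242 genes, 78 higher and 164 lower in the knockdown libraries, where 683.4 are expected by chance. DESeq2 also called 0 genes, with 546 at an unadjusted p under 0.05, and limma-voom called 0, with 117. All 3 knockdown libraries lay on one side of all 3 controls for 853 genes, or 6.24%, where chance gives 10%. The smallest p among genes higher in the knockdown belonged to GLB1L2, a beta-galactosidase-like gene, at 2.37 ± 1.26 against 0.385 ± 0.0717 CPM (log2 difference 2.60, SE 0.59). TNFAIP6, ATP2B2, LOXL4 and SNORD48 followed, with log2 differences of 2.15, 2.24, 1.68 and 1.33. All were near the floor, at means of 0.951, 1.17, 3.79 and 2.12 CPM in the knockdown libraries. Their control means were 0.206, 0.239, 1.18 and 0.836 CPM. On the lower side, FAM116B had a log2 difference of −1.65 (SE 0.47) and JPH2, a junctophilin, one of −1.76, at 10.8 ± 1.71 against 36.4 ± 23.1 CPM. DNAJC5B, SH3D21 and IZUMO4 had −2.50, −2.50 and −2.73, at knockdown means of 0.503, 1.15 and 1.48 CPM. Their highest control values, 5.32, 12.7 and 20.8 CPM, were in the library labelled scrambled control 2. Each of these 10 genes had an edgeR adjusted p of 0.926.

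The spread between libraries of one group was wide. The biological coefficient of variation was 0.373, and the median SE of a log2 difference was 0.33. In log2 CPM, the library labelled scrambled control 2 correlated with controls 1 and 3 at 0.923 and 0.876 across genes. Controls 1 and 3 correlated at 0.967, the knockdown libraries with one another at 0.955 to 0.969, and knockdown 3 with control 3 at 0.995. Genes are not independent replicates, so these values describe the libraries only. EEF1A1, a translation elongation factor gene, took 3.50% of the counts in the library labelled scrambled control 2 and 1.89% to 2.86% in the other 5.

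**Figure D2:**
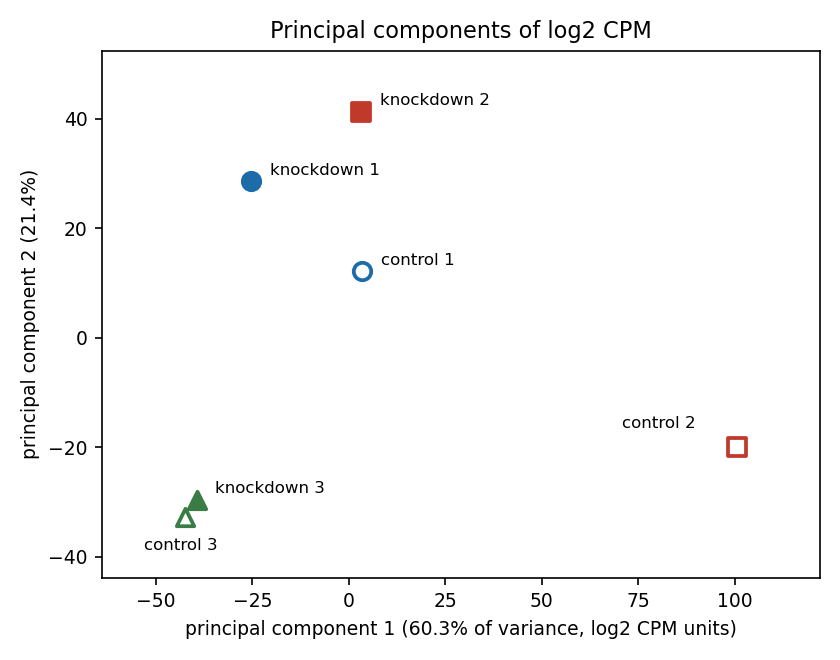
Principal components of log2 CPM over the 13668 tested genes; axes are component scores in log2 CPM units with the percent of variance, filled symbols are knockdown and open symbols control libraries, and shapes give the replicate number. The library labelled scrambled control 2 lies at 100.5 on the first component and the other 5 between −42.4 and 3.48; knockdown 3 and control 3 lie side by side.

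Gene lists fixed beforehand were compared with all other tested genes by camera (limma) with a preset inter-gene correlation. Of 28 lists tested, 10 had an adjusted p under 0.05, 5 higher and 5 lower in the knockdown libraries. None did with an estimated correlation, where the adjusted p was 0.833 for each of the 10. The fry test asks another question, whether a list's genes move on balance in one direction, without comparing them with other genes, and its smallest adjusted p was 0.892. No member of any list passed, either over all genes or adjusted over the list alone. A setting that bears on every direction given here left out the library labelled scrambled control 2. There, 7 of the 10 lists were called, 5 of them in the same direction. With an estimated correlation none was called without that library (smallest camera adjusted p = 0.874). Without it, 79 of the 124 named genes had a log2 difference that was over 1.5 times smaller or had turned, 9 of them having turned.

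Genes of cholesterol and sterol synthesis had the largest median difference among the called lists. All 20 tested members were lower in the knockdown libraries, with a median log2 difference of −1.48 (camera adjusted p = 3.13e-09; adjusted p = 0.833 with an estimated correlation). HMGCS1, the synthase that makes HMG-CoA, was at 43.0, 137 and 85.3 CPM in the knockdown libraries and at 140 and 89.9 CPM in controls 1 and 3, against 1402 CPM in the library labelled scrambled control 2. LSS, lanosterol synthase, had a log2 difference of −1.69 (SE 0.66), HSD17B7 one of −2.10 and FDPS one of −1.22. Without the library labelled scrambled control 2, HMGCS1, LSS, HSD17B7 and FDPS had −0.38, −0.61, −0.36 and −0.54. The list's median was −1.39 in pair 1, −2.19 in pair 2 and −0.03 in pair 3. The call and its direction held without each library in turn, and without the library labelled scrambled control 2 the camera adjusted p was 0.000115. Against the mean of the 6 libraries, the list's median was 2.13 in the library labelled scrambled control 2 and −1.45 in knockdown 1. It was −0.04 and −0.33 in knockdown 2 and 3, and −0.04 and −0.35 in controls 1 and 3. Leaving out 1 library at a time cannot remove both outlying libraries, so the call is no sign of a shift shared by the groups.

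Genes of the ATF4 and unfolded protein response were higher for 19 of 25 members, with a median log2 difference of 0.29 (camera adjusted p = 0.00258; adjusted p = 0.833 with an estimated correlation). SLC7A11, the cystine transporter subunit, had a log2 difference of 2.11 (SE 0.77), at 325, 348 and 55.9 CPM in knockdown 1 to 3 and 92.6, 18.9 and 57.7 CPM in the libraries labelled control 1 to 3. CHAC1, PSAT1 and ASNS had log2 differences of 2.21, 1.35 and 1.15. Pair medians were 0.73, 0.60 and −0.02 in pairs 1 to 3. The call was lost without knockdown 1 (camera adjusted p = 0.0824) and without control 3 (0.0557).

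MYC targets and ribosome biogenesis genes were higher for 28 of 30 members (median log2 difference 0.52, camera adjusted p = 9.1e-07). NOP58, NOP2, WDR12 and DKC1, which act in ribosome assembly or RNA modification, had log2 differences of 0.78, 0.67, 0.61 and 0.51. The adjusted p was 0.833 with an estimated correlation, and the camera call was lost without the library labelled scrambled control 2 (adjusted p = 0.0923). In pairs 1 to 3 the list's median was 0.58, 1.62 and −0.07. Without both libraries numbered 2, where pairs 1 and 3 remain, the list was called higher with the preset correlation (camera adjusted p = 7.31e-08). That setting was not run with an estimated correlation. Cytosolic ribosomal protein genes lay the other way, 31 of 33 lower with a median log2 difference of −0.23 (camera adjusted p = 0.0180; adjusted p = 0.833 with an estimated correlation), RPL4 and RPL11 at −0.43 and −0.45. Their direction turned without the library labelled scrambled control 2, to higher with a camera adjusted p of 0.0158, and the call was lost without knockdown 3 (0.639). Spliceosome and splicing factor genes, whose Sm proteins are PRMT5 substrates, were higher for 21 of 30 members and not called (median 0.14, camera adjusted p = 0.250), with LSM4 at 0.37 and SRSF5 at −0.47. They were called higher without knockdown 2 (camera adjusted p = 0.0258) and without control 3 (0.0231), and their direction was lower without the library labelled scrambled control 2 (0.554).

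All 28 G2/M genes were lower in the knockdown libraries (median log2 difference −0.31, camera adjusted p = 0.00258; adjusted p = 0.833 with an estimated correlation), although under upper quartile scaling and under total counts 1 of them was higher. NEK2, a centrosomal kinase, had −0.74, CDC25C −0.57, TTK −0.39 and KIF2C −0.38. The G2/M call was lost without knockdown 2 (camera adjusted p = 0.564), control 1 (0.0521) or control 3 (0.691). Without the library labelled scrambled control 2 the G2/M camera adjusted p was 1.56e-14 with the preset correlation and 0.874 with an estimated one. Over all libraries the estimated correlation of the G2/M genes was 0.814. G1/S genes were higher for 21 of 28 members (median 0.16, camera adjusted p = 0.0320; adjusted p = 0.833 with an estimated correlation), PCNA at 0.53, CCNE2 at 0.56 and CDT1 at −0.50. Without the library labelled scrambled control 2 the G1/S list was lower (camera adjusted p = 0.0120), as the G2/M list was with and without it, and no test compared the lists. The G1/S call was lost without knockdown 2 (0.143), without knockdown 3 (0.782) and under total counts (0.0526).

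Among p53 targets, 17 of 25 members were higher (median log2 difference 0.13, camera adjusted p = 0.0215; adjusted p = 0.833 with an estimated correlation). BAX, a pro-apoptotic BCL2 family gene, was at 168, 141 and 105 CPM in the knockdown and 75.1, 97.1 and 85.6 CPM in the control libraries, a log2 difference of 0.68 (SE 0.24). MDM2, SESN2 and AEN had 0.62, 0.84 and 0.72, and CDKN1A, the p21 gene, had 0.96 (SE 0.51). With the replicate number as a block the list's camera adjusted p was 0.0558. The call was also lost without knockdown 1 (0.338), control 1 (0.531) or control 3 (0.624). Without the library labelled scrambled control 2 the camera adjusted p was 3.01e-13 with the preset correlation and 0.874 with an estimated one. The list's medians were 0.75, −0.46 and 0.22 in pairs 1 to 3. Genes of the BCL2 family and caspases were not called, with 13 of 28 higher, a median of −0.02 that was positive under upper quartile scaling and total counts, and an adjusted p of 0.876 (camera). Their direction was lower with all libraries and higher without knockdown 3 (0.812) or the library labelled scrambled control 2 (0.447).

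The MLL-fusion and HOXA program was lower for 19 of 25 members (median log2 difference −0.36, camera adjusted p = 0.00258; adjusted p = 0.833 with an estimated correlation). MEIS1, the HOXA9 cofactor, was at 24.1, 18.3 and 29.6 CPM in the knockdown libraries, at 32.2 and 32.9 CPM in controls 1 and 3, and at 102 CPM in the library labelled scrambled control 2. HOXA3, HOXA4 and HOXA11 had log2 differences of −1.07, −1.97 and −0.93. Without the library labelled scrambled control 2, MEIS1, HOXA3, HOXA4 and HOXA11 had −0.44, −0.71, −0.46 and −0.50. The call was lost without knockdown 2 (camera adjusted p = 0.142) and without both libraries numbered 2 (0.374). STAT5 and MAPK targets downstream of FLT3-ITD were lower for 17 of 25 members and not called (median −0.16, camera adjusted p = 0.341), with PIM3 at −1.64 (SE 0.78) and at 0.020 without the library labelled scrambled control 2. The list was called lower without knockdown 2 (camera adjusted p = 0.0379), and its direction turned without knockdown 3 (0.812) and without the library labelled scrambled control 2 (0.786).

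Of the differentiation lists, neutrophil granule genes were called higher, 12 of 15 members (median log2 difference 0.61, camera adjusted p = 0.0139; adjusted p = 0.833 with an estimated correlation). ELANE and PRTN3, which encode granule proteases, had 0.66 (SE 0.40) and 0.73 (SE 0.42), and CXCR2 had 0.96. That call was lost without knockdown 2 (camera adjusted p = 0.398), control 3 (0.0688) or the library labelled scrambled control 2 (0.172), without both libraries numbered 2 (0.934) and with no count filter (0.0595). Monocyte and macrophage markers were higher for 12 of 19 members (median 0.14, camera adjusted p = 0.566), with ITGAX at −2.21 (SE 1.17), and their direction was lower without the library labelled scrambled control 2 (0.554) and without knockdown 2 (0.843). Stem and progenitor markers divided evenly, 4 higher and 4 lower (camera adjusted p = 0.520). Glycolysis and hypoxia genes were called lower, 20 of 26 members (median −0.43, camera adjusted p = 0.00611; adjusted p = 0.833 with an estimated correlation). ENO2 had −4.26 (SE 1.98) and ADM −2.88, while PFKFB3 had 0.70. The library labelled scrambled control 2 held 361 CPM of ENO2, against 46.9 and 0.518 CPM in controls 1 and 3, and 155 CPM of ADM, against 25.1 and 2.43 CPM. Without it ENO2 had −1.73 and ADM −0.73, and in pair 3 they had 0.27 and 0.28. The hypoxia call was lost without knockdown 3 (camera adjusted p = 0.187), control 1 (0.172) or the library labelled scrambled control 2 (0.0991). In pairs 1 to 3 the hypoxia list's median was −0.75, −0.67 and 0.001. Without both libraries numbered 2, where pairs 1 and 3 remain, it was called lower with the preset correlation (camera adjusted p = 0.000124). That setting was not run with an estimated correlation.

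**Figure D3:**
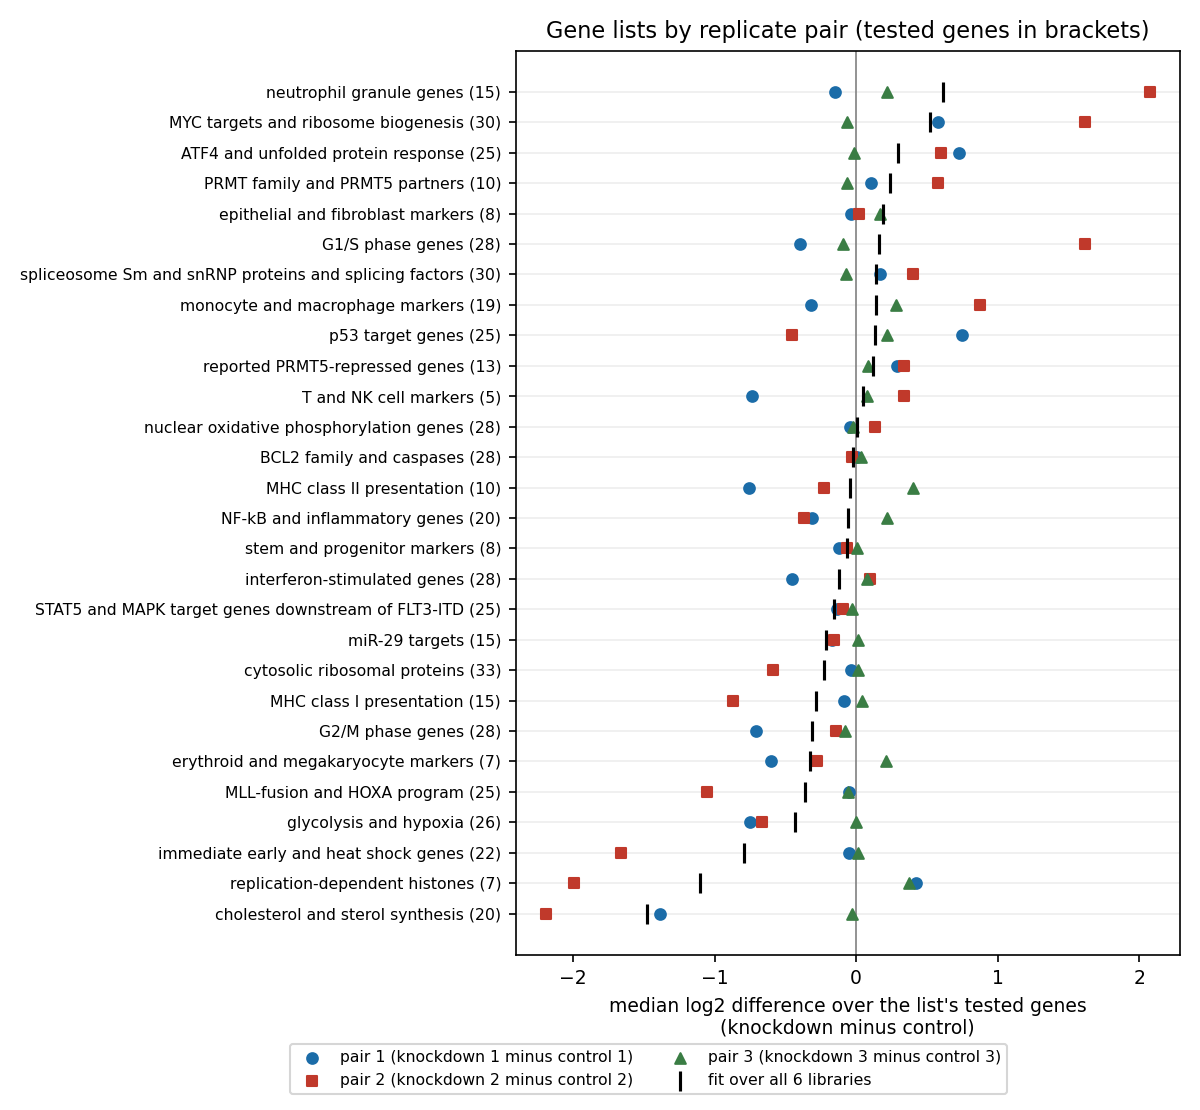
Median log2 difference of each of the 28 tested lists (knockdown minus control, x axis), for each pair of libraries with the same number and for the fit over all 6 libraries (black ticks); numbers in brackets are tested genes. Pair 2 holds the library labelled scrambled control 2; cholesterol genes were at −2.19 in pair 2 and −0.03 in pair 3.

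The lists nearest to the study's question were not called. PRMT family and partner genes were higher for 6 of 10 members (median log2 difference 0.24, camera adjusted p = 0.382), PRMT1 at 0.37 and PRMT3 at 0.45, and the direction was lower without the library labelled scrambled control 2 (0.616). Genes reported as repressed by PRMT5 were higher for 9 of 13 members (median 0.12, camera adjusted p = 0.283), with the tumour suppressor gene ST7 at 0.80 (SE 0.36) and CDKN2C at −0.77. miR-29 targets were lower for 10 of 15 members (median −0.22, camera adjusted p = 0.180), TET2 at −0.65 and MCL1 at −0.57. Interferon-stimulated genes, which a viral vector can induce, were lower for 17 of 28 members (median −0.12, camera adjusted p = 0.444), with STAT2 at −0.89, and their direction turned without knockdown 1 (0.928). NF-kB genes were lower for 11 of 20 members, with a median of −0.06 that turned positive under total counts and a camera direction of higher (adjusted p = 0.864), which turned with the replicate block (0.797) and without knockdown 2 (0.633), knockdown 3 (0.921), control 1 (0.721) or control 3 (0.752). CD83 had 0.69 (SE 0.27) and PTGS2 −1.40.

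MHC class I genes were lower for 12 of 15 members and not called (median −0.28, camera adjusted p = 0.0546), HLA-E at −0.84 and HLA-F at −0.65. They were called under upper quartile scaling (camera adjusted p = 0.0495), without knockdown 3 (0.0186) and without control 1 (0.0301), and had 0.417 without the library labelled scrambled control 2, where HLA-E was at −0.11 and HLA-F at 0.029. MHC class II genes were lower for 7 of 10 members (median −0.04, positive under total counts; camera adjusted p = 0.372). Leaving out 1 library called them in opposite directions, higher without knockdown 1 (0.0388) and lower without knockdown 3 (0.00287), and their direction turned without the library labelled scrambled control 2 (0.997). The nuclear oxidative phosphorylation genes were higher for 15 of 28 (median 0.00, negative under RLE scaling; camera adjusted p = 0.799), with a direction of lower without knockdown 3 (0.396), control 1 (0.931) or the library labelled scrambled control 2 (0.159). Immediate early and heat shock genes were lower for 16 of 22 members (median −0.80, camera adjusted p = 0.0546), FOS at −2.14 (SE 0.76), EGR1 at −2.66 and ZFP36 at −1.44. This list was called with the replicate number as a block (camera adjusted p = 0.0415), under upper quartile scaling (0.0456), under total counts (0.0247), without control 1 (0.00636) and without control 3 (0.0310). Its direction turned without the library labelled scrambled control 2 (0.678), where FOS, EGR1 and ZFP36 had −0.67, −0.31 and −0.71. Replication-dependent histones, 7 tested of 21, had a median of −1.10 (camera adjusted p = 0.827), HIST1H1C at −4.43 (SE 1.49) and HIST1H2BK at 0.78. HIST1H1C was at 92.9 CPM in the library labelled scrambled control 2 and at 5.11 and 1.09 CPM in controls 1 and 3, and had −1.02 without that library. The histones were called higher without both libraries numbered 2 (0.0282), and their direction turned without knockdown 2 (0.779), knockdown 3 (0.812) or the library labelled scrambled control 2 (0.0964). In the library labelled scrambled control 2 the median of these histones was 2.08 above the other controls, and that of the immediate early and heat shock genes 1.94 above.

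Markers of other cell types were few. Erythroid and megakaryocyte markers were lower for 5 of 7 tested members (camera adjusted p = 0.444), and their direction turned without the library labelled scrambled control 2 (0.802). T and NK cell markers had 5 tested members, a median of 0.05 and a camera direction of lower (adjusted p = 0.639), which turned without knockdown 1 (0.928), knockdown 3 (0.534) or control 1 (0.490). Epithelial and fibroblast markers were higher for 5 of 8, with a median of 0.19 and a mean of −0.11 (camera adjusted p = 0.639), ACTA2 at 0.90 (SE 0.27) and KRT8 at −1.43, and their direction turned without knockdown 2 (0.591) or control 3 (0.456). B cell markers had 3 tested members, too few for the test, with PAX5 at 0.16 and BLNK at 0.85. Mitochondrially encoded genes were not analysed here.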

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

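Settings without both libraries numbered 2, sample quality weights, robust estimates, the block without the library labelled scrambled control 2, and the estimated correlation without that library were chosen after seeing the data. No gene passed under any planned or added setting, and the PRMT5 log2 difference stayed below 0, from −0.97 to −0.29, with a smallest adjusted p of 0.719. In the planned edgeR, DESeq2 and limma-voom fits, the smallest adjusted p of any of 124 named genes was 0.524. Named genes were not read out under the 2-fold minimum and glmTreat settings. Under the added settings only PRMT5 was read out. Counts at an unadjusted p under 0.05 (242) were 477 without a count filter, 436 with the replicate block, 546 by DESeq2, 117 by limma-voom, 733 with quality weights, 158 with a 2-fold minimum, 54 without both libraries numbered 2, and 33 to 1307 with 1 library left out. DESeq2 gave no adjusted p for 4789 of 23698 rows.

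With the replicate block the PRMT5 log2 difference was −0.50, with 0 genes and 10 lists called. The block changed no other call than those of the p53 and immediate early lists. Lists called numbered 10, and 9 to 12 under the scalings and filters, 7 to 9 with 1 library left out and 8 without both libraries numbered 2. They were 0 with the estimated correlation and 0 with it without the library labelled scrambled control 2. By fry, which tests a list against no change and not against other genes, they were 0.

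Of the named genes' values under alternatives, 1694 kept their direction and 18 turned; the cause was not tested. DNMT3A had 0.0048 under total counts and 0.0087 by limma-voom, and PRF1 had −0.12 with the replicate block and −0.31 by limma-voom. With 1 library left out, ranges were −0.32 to 0.22 for DNMT3A, −2.07 to 0.020 for PIM3, −1.14 to 0.11 for KIT, −0.14 to 0.80 for IL7R, −1.42 to 0.95 for PRF1, −0.076 to 0.0099 for NCAM1, −0.14 to 0.50 for PAX5, −1.91 to 0.21 for PTGS2, −0.92 to 0.029 for HLA-F, −1.57 to 0.0092 for HIST1H3D and −4.68 to 0.74 for HIST2H2BE.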

Other observations

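All tests of explanations in this part were chosen after the results were seen, and the bound of the scale factor test was set again after its first value. Leaving out 1 library was a planned setting, but reading it as a test of an explanation was not planned. Pair 3, knockdown 3 against control 3, was the closest pair and held the largest difference in PRMT5. Over 8602 genes with a mean log2 CPM of at least 4, the SD of the log2 difference was 0.122 in pair 3, against 0.450 in pair 1 and 0.867 in pair 2. PRMT5 was the lowest of these genes in pair 3, at −1.58, and the only one over 2-fold. The next lowest was C21orf56 at −0.50. Names here and in the next sentence were chosen after their values were seen. The highest in pair 3 were COL9A2 at 0.79, AHNAK2 at 0.70, the fractalkine receptor gene CX3CR1 at 0.68, CACNA1E at 0.67, the integrin gene ITGAM at 0.67, TPM2 at 0.65 and the complement gene C3 at 0.62. Of these, ITGAM was at −2.18 in pair 1 and −0.44 in pair 2, and C3 at 0.93 and 2.69. Each pair is 1 library against 1, with no replicate check.

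In the other pairs, 271 genes in pair 1 and 1916 in pair 2 differed by over 2-fold. The highest were GDF15, a stress-induced cytokine gene, at 2.76 in pair 1 and the calprotectin gene S100A8 at 4.96 in pair 2, and the lowest were HSPA7, a heat shock pseudogene that can share reads with its relatives, at −5.12 in pair 1 and CREBRF at −4.01 in pair 2. All 4 were named after their values were seen. In pair 2, PRMT5 was higher by 0.43 in the knockdown library than in the library labelled scrambled control 2, whose PRMT5 value goes against its label.

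The absence of genes past the threshold was weighed first. Leaving out the library labelled scrambled control 2 gave 0 genes with edgeR, and 103 at an unadjusted p under 0.05, which argues against calls hidden by that library alone, though 5 libraries make a weaker test than 6. All 10 splits of the 6 libraries into 3 and 3 gave 0 genes at an adjusted p under 0.05 with edgeR, the real one included (highest other 0); 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 242 genes and the highest other 2200, with knockdown 1, knockdown 3 and control 3 against the rest, which points to a structure of the libraries other than the groups. Among the splits that part all 3 pairs, the others gave 246, 99 and 50.

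The library labelled scrambled control 2 stood apart from the other controls: after scaling, 2066 genes were over 2-fold higher and 2074 over 2-fold lower than the mean of controls 1 and 3 (control 1 against control 3: 1058 higher, 124 lower), and differences of that number on both sides argue against a single scale factor or depth, while GC content with transcript length explained 1.79% of the variance of its differences. Its correlation with the knockdown libraries was at most 0.909, below the 0.955 to 0.969 among them. This argues against a knockdown library under a control label as the only cause of its distance. Its correlations with controls 1 and 3, at 0.923 and 0.876, were likewise below the 0.967 between those controls. The distance of this library therefore cannot tell which label is right. For its PRMT5 level alone, a swap cannot be told apart from other causes: the highest knockdown value was 103 CPM against 133 CPM in the lower of the other controls, too near for their spread. A different state of the culture stays open as well: glycolysis and hypoxia genes had a median of 1.25 above the other controls, but they were 1 of 10 lists, of 28, above the central 95% of 10000 random lists matched on expression, 7 lists lay below it, and random lists leave out the correlation between genes.

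In the same library, against controls 1 and 3, cholesterol genes lay 2.33 above and MYC and ribosome biogenesis genes were at −1.77. PRMT family and partner genes, PRMT5 included, were at −0.97. The design names no biological difference for this library. Apart from the state of the culture, which the hypoxia list could not decide, none was tested.

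The called lists were set against the size of the PRMT5 difference by pair. In 8 of the 10 called lists the median difference was smallest in size in pair 3, where PRMT5 differed most; the exceptions were the MLL-fusion and HOXA program and the neutrophil granule genes. In size, no called list exceeded 0.22 in pair 3 on the log2 scale. Genes in general also differed least in pair 3. Over 8602 genes the median absolute log2 difference was 0.0706 there, against 0.243 in pair 1 and 0.539 in pair 2. The count of 8 therefore says little about PRMT5, and no random lists were set beside it. With 3 pairs, one of which holds the library labelled scrambled control 2, an effect of PRMT5 loss and unrelated differences between cultures cannot be told apart.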
